A study of Homo sapiens with 2 samples.

How the data were processed

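DNA binding of human ETS1 and EGR1 was measured on double-stranded oligonucleotide microarrays, with 1 array per protein. Per the labels, ETS1 was the full-length protein with the change W356C and EGR1 was its DNA-binding domain. Both carried a GST tag, were expressed in E. coli and were detected with a fluorescent antibody against the tag. The probes are written over 6 letters. M stands for 5-methylcytosine and W for a guanine whose partner on the other strand is 5-methylcytosine, so that M pairs with W.

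The deposited value of a probe is a score which the authors standardised within each array: over its 47061 probes it has a mean of 0 and an SD of 1.0. How scanner brightness became this score, and whether the scale before standardising was linear or logarithmic, is not given in the sources used here. The ETS1 scores ran from -1.14 to 85.2 with a median of -0.0807, and the EGR1 scores from -2.76 to 20.5 with a median of -0.226. Because the score has no true zero, no fold was computed and only differences are given. A single value recurred on each array, at 232 ETS1 probes (-0.0807) and at 182 EGR1 probes (-0.219), and these probes were kept.

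The tests had been planned for log2 intensity, which such a score does not allow. Each probe's rank on its array was therefore turned into a standard normal deviate, called the normal score here, which is the same for any monotone scale. Its mean over an array is 0, and higher means brighter. This replacement was decided after the unit was known and after summaries per 6-mer had been looked at. The means, permutation tests and least squares fits stayed as planned, and the deposited score itself was used as an alternative.

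A listed sequence has 31 letters, with the 3 constant letters GCG at each end and 25 variable letters between them. A 6-mer was pooled with its reverse complement, which gives 23436 sites, and was read in the variable part. Each non-palindromic 6-mer lay in at least 33 probes, as the design states, and the median was 40 probes. Of the 48000 spots of the stated layout, 939 were not analysed here. Each protein has 1 array, so an error given with a value is the SD over the probes that hold a site, or the standard error made from it. All p-values measure the spread between probes of 1 array and not between repeated experiments. Overlapping 6-mers share probes and are not independent.

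The choices that follow were made before the data were examined. Each 6-mer received a rank enrichment score E between -0.5 and 0.5, which sets the brighter part of the probes with the site against the brighter part of those without it, and 0.45 was the limit for specific binding. For the 553 6-mers with exactly 1 CpG, probes with the CpG as MW (5-methylcytosine on both strands), MG or CW (on 1 strand) were compared with probes with CG. These used two-sided permutation tests of the mean with 100000 resamples, whose smallest p is 1e-05. Benjamini-Hochberg adjustment was applied over each family, with a limit of 0.05. In the 6-letter seeds CCGGAA, CGGAAG and GGAAGT of ETS1 and GCGTGG, CGTGGG, GTGGGC and TGGGCG of EGR1, each letter was replaced by each of the other 5 letters and tested in the same way. Additive models gave 1 coefficient per C or G of a longer site, with p-values from permuted residuals (Freedman-Lane). For the 9-letter EGR1 site at least 30 probes were required. The set of unmodified 6-mers with GGAA, and the set with 5 or more letters in a row of GCGTGGGCG, were set against 10000 random sets of the same size.

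The sites named are the seeds and longer sites with their M and W replacements and the largest and smallest replacement of each seed. Also named, per protein, are the 10 4-letter 6-mers with the highest mean over all their modified and unmodified versions, the 5 unmodified and 5 modified 6-mers with the highest E, and the 5 largest rises and 5 largest falls past the limit in the CpG family. Any other site is said to be chosen after its value was seen. The EGR1 list by mean over all versions is not reported here.

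On simulated data the CpG test recovered, of 50 planted shifts each on the ETS1 array, 8 at 0.5, 22 at 1.0, 44 at 1.5 and 49 at 2.0 normal score units. On the EGR1 array it recovered 5, 25, 43 and 50. With nothing planted it called 0 of 553 on either array. Beside planted sites it also called 20 (ETS1) and 28 (EGR1) of 353 unplanted 6-mers, which overlap planted ones and share their probes. Where planted 6-mers shared a probe, the larger shift replaced the smaller. Some 6-mers thus did not carry their nominal shift, so the recovered numbers may understate the power of the test. Only 353 of the 553 6-mers were unplanted, and many true shifts ease the Benjamini-Hochberg limit. For a family with few shifts the recovered numbers may therefore overstate the power as well. Shuffled scores put 0 of 23436 6-mers above the E limit.

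The restriction to 6-mers without GGA and a product term for both strands of the CpG were added after the data were seen. The other alternatives were the median in place of the mean, the deposited score, removal of letter composition by least squares and a search of the whole probe. Others took only sites before or only sites after the middle of the probe, left out probes with a further strong site, the brightest 1% or the dimmest 10% of probes, or used odd-numbered or even-numbered probes alone. A local median over 5 by 5 spots was subtracted, a rank test and stricter or looser limits were tried, and the family was restricted to strong 6-mers. The local median takes the probe number as a spot position with 150 columns, which no header states. The rank correlation between probes whose numbers differ by 150 was 0.108 for ETS1 and 0.0674 for EGR1, against -0.0090 and 0.0109 at 160. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.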

Results

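The data are 1 universal protein-binding array for full-length ETS1 with the change W356C and 1 for the DNA-binding domain of EGR1. ETS1 is an ETS family transcription factor whose textbook core is GGAA, and EGR1 a zinc finger factor whose textbook site is GCGTGGGCG. No ETS1 array without W356C is included, so values for ETS1 describe this protein only. A difference between the arrays cannot be told apart from an effect of W356C or of the unlike lengths of the proteins. Both arrays carry the same 47061 probes, in which cytosine can be 5-methylcytosine at any position, on either strand, within CpG or outside it. A probe held 8.33 modified letters on average, from 0 to 20. The comparisons ask which sites each protein prefers and how 5-methylcytosine at each position changes its score. Values are mean normal scores over the probes with a site, with the SD over those n probes, and there are no replicate arrays.

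ETS1 bound sites built on GGA. Of 23436 6-mers, 58 had E above 0.45, and all 58 held GGA when M is read as C and W as G, against 14.6% of all 6-mers. GGAA was present in 36 of them and GGAT in 16. Without the brightest 1% of probes, a cut made on the score itself, 29 6-mers were above the limit. The highest unmodified 6-mers by E were CCGGAA (E 0.493, mean 2.09 ± 1.06, n = 40), CGGAAG (E 0.488, 2.09 ± 0.65, n = 38), the palindrome TCCGGA (E 0.485, 1.63 ± 1.03, n = 23), CAGGAA (E 0.479, 1.26 ± 1.59, n = 41) and CCGGAT (E 0.477, 1.55 ± 1.12, n = 42).

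Modified sites reached E values as high as unmodified ones on the ETS1 array. The 5 highest were CWGAAW (E 0.495, mean 2.33 ± 0.68, n = 38), CGGAAW (E 0.494, 2.22 ± 0.83, n = 45), CCWGAA (E 0.494, 2.04 ± 1.10, n = 40), CWGATW (E 0.493, 2.15 ± 0.85, n = 42) and CWGAAG (E 0.491, 2.15 ± 0.77, n = 41). In all of them the modified cytosine lies opposite a G of the GGA strand. By number of modified letters, 12 of 2080 6-mers with 0 were above the limit (0.577%), 26 of 6144 with 1 (0.423%), 16 of 7728 with 2 (0.207%) and 4 of 5120 with 3 (0.0781%). No 6-mer with 4 or more passed, and the highest E there was 0.318.

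Averaged over all versions of a site, so that the choice favours neither modified nor unmodified forms, GGAAGT led the ETS1 list with 1.49 over 8 versions, whose means ran from 1.15 to 2.05. GGATGT followed with 1.09 (versions from 0.458 to 1.61) and CGGAAG with 1.06 (versions from -0.0530 to 2.33). The rest of the first 10 were AGGAAG (0.977), GGAAAT (0.933), CGGATG (0.869), CCGGAA (0.785), GGAAGC (0.785), AGGATG (0.748) and CGGAAA (0.702). The sites whose versions spread widest, CGGAAG, CCGGAA, CGGATG and CGGAAA, hold a CpG directly at the core.

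Methylation of that CpG on both strands lowered the ETS1 score. CGGAAG fell from 2.09 ± 0.65 with CG (n = 38) to -0.0530 ± 1.11 with MW (n = 39), a difference of -2.14 (SE 0.21, adjusted permutation p = 0.000614). CGGAAA differed by -1.89 (SE 0.22), CCGGAA by -1.89 (SE 0.26), CCGGAT by -1.53 (SE 0.26) and ACCGGA by -1.52 (SE 0.27), each with the same adjusted p. These are the 5 largest falls. In the whole family of 553 6-mers, 28 fell and 0 rose past adjusted p 0.05, while 85 were lower and 4 higher at an unadjusted p under 0.05. CGGA is present in 19 of the 28, and GGA in 21, against 46 and 68 of the 553. The count was 16 with letter composition removed, 16 without the brightest 1% of probes and 14 at an adjusted p limit of 0.01. With part of the probes it was 9 (odd-numbered) and 7 (even-numbered), and with part of each probe 11 (before the middle) and 10 (after it).

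**Figure D1:**
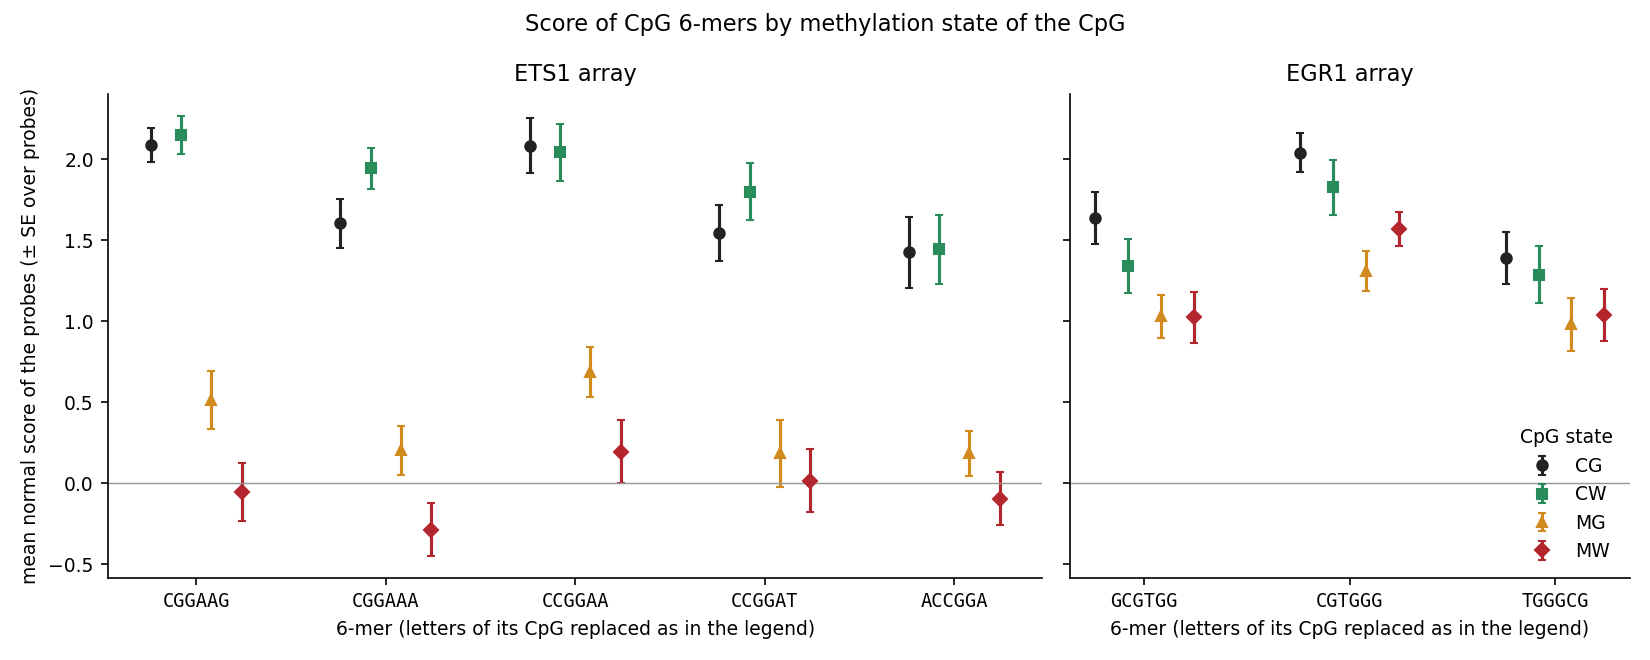
Mean normal score (vertical axis, bars are the SE over probes) of CpG 6-mers with the CpG unmethylated (CG), methylated on the other strand (CW), on the written strand (MG) or on both (MW). On the ETS1 array CG and CW lie together and MG and MW lie below them, with CGGAAG at 2.09, 2.15, 0.513 and -0.0530; on the EGR1 array all states of the 3 sites lie at 0.981 or above.

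The strand of the modified cytosine separated the ETS1 sites. With 5-methylcytosine on the GGA strand alone, MGGAAG had 0.513 ± 1.13 (n = 41), a difference of -1.57 from CGGAAG (SE 0.21, adjusted permutation p = 0.000922). CMGGAA differed by -1.40 from CCGGAA (SE 0.23) and MGGAAA by -1.40 from CGGAAA (SE 0.21), with the same adjusted p. With 5-methylcytosine on the other strand alone, CWGAAG had 2.15 ± 0.77 (n = 41), a difference of 0.0640 with a 95% interval from -0.250 to 0.378 (adjusted permutation p = 0.956). Over the whole probe that difference was 0.467 and passed the limit. There CGGAAG gains sites that begin in the unmodified GCG at the start of the probe, which CWGAAG cannot. The forms then lie at unlike places, so that value does not single out 5-methylcytosine. For CCWGAA the difference was -0.0427, with an interval from -0.517 to 0.432, and for CWGAAA it was 0.338, from -0.0449 to 0.722. In the family counts each 6-mer is read on its alphabetically first strand, so MG and CW there do not tell the GGA strand from the other. For example, CMGGAT against CCGGAT (-1.36, adjusted permutation p = 0.00276) counts as a fall with CW. Read so, 9 fell with MG and 7 with CW, and 0 rose in either. At an unadjusted p under 0.05, 56 were lower and 4 higher with MG, and 39 lower and 0 higher with CW. Over 13 alternatives the count of falls ran from 2 to 11 with MG and from 0 to 7 with CW.

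**Figure D2:**
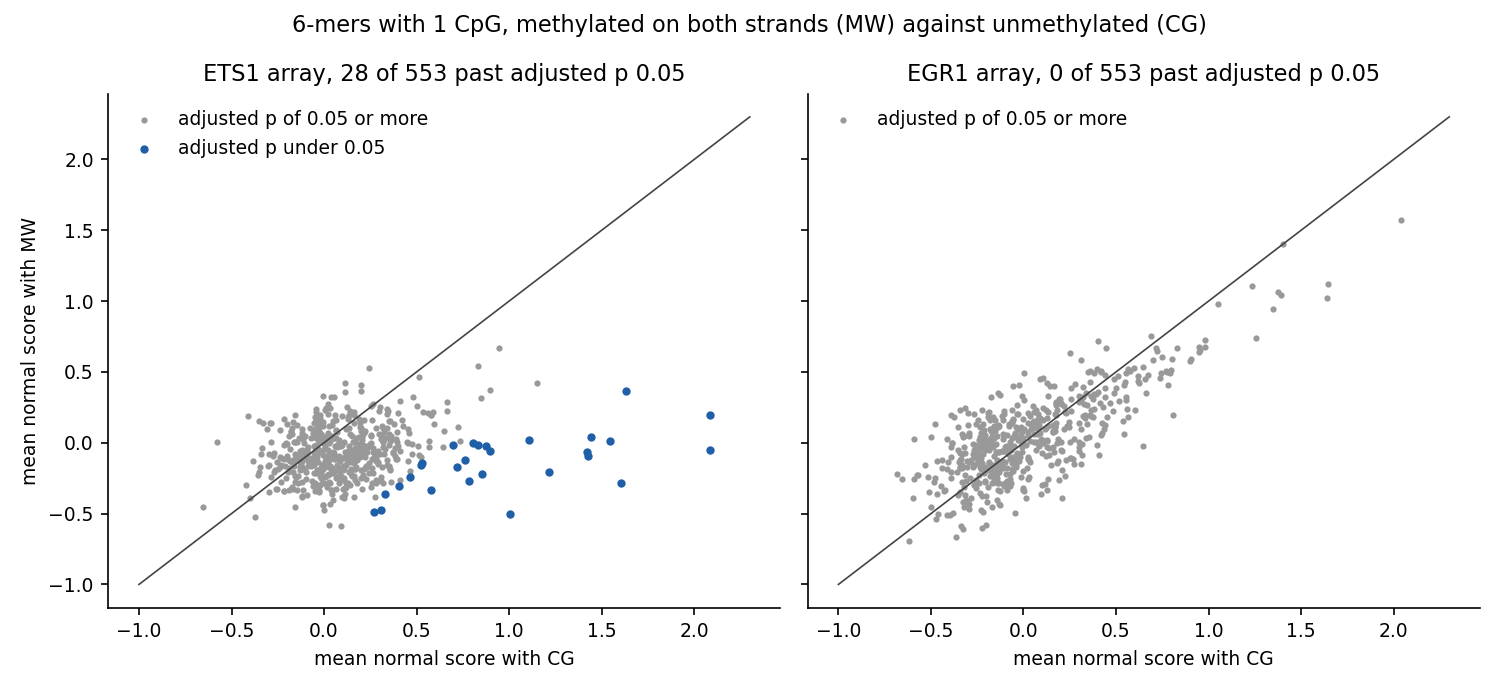
Mean normal score of each of 553 6-mers with 1 CpG methylated on both strands (vertical axis) against the same 6-mer unmethylated (horizontal axis), with the line of equal scores. Coloured points passed adjusted p 0.05, which 28 did on the ETS1 array, all below the line, and 0 did on the EGR1 array.

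Replacing letters of the ETS1 seeds by other bases, modified or not, lowered the score in 76 of 79 cases. The lowest of each seed were CGTAAG, which differed by -2.39 from CGGAAG (SE 0.17), CCGMAA by -2.29 from CCGGAA (SE 0.235) and GTAAGT by -1.74 from GGAAGT (SE 0.24). Of 11 replacements by the modified form of the same base, 5 lowered the score and 0 raised it. Those 5 were MGGAAG (-1.57), CMGGAA (-1.40), MCGGAA (-1.03, adjusted permutation p = 0.000242), CGWAAG (-0.806, adjusted p = 0.000274) and CCGWAA (-0.612, adjusted p = 0.0143). Without the brightest 1% of probes MCGGAA differed by -0.629 and CCGWAA by -0.168, neither past the limit, and CCGWAA ended in 3 of 12 alternatives. CGWAAG did not pass with odd-numbered probes (-0.538). The least negative or highest values of each seed were CCWGAA (-0.0427), CGGAAW (0.134, adjusted permutation p = 0.438) and GGAAWT (0.244, adjusted p = 0.291), none past the limit. WGAAGT had a difference of -0.174 (adjusted permutation p = 0.536) and GWAAGT of -0.338 (adjusted p = 0.25).

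In longer ETS1 sites the C next to the GGA core carried the largest coefficient. Over 203 probes with CCGGAAG, 5-methylcytosine at the C of position 2 gave -1.75 (SE 0.13, adjusted permutation p = 3.5e-05) and at the C of position 1 gave -0.710 (SE 0.13, adjusted p = 3.5e-05). Opposite the G of position 3 it gave 0.168 (SE 0.13, adjusted permutation p = 0.297), and opposite position 7 0.297 (SE 0.13, adjusted p = 0.0576). Opposite the second G of GGA the coefficients were -0.254 in CCGGAAG (adjusted permutation p = 0.105), -0.266 in CGGAAGT (adjusted p = 0.152) and -0.226 in CCGGAAGT (adjusted p = 0.483), none past the limit, although CGWAAG and CCGWAA were. In a fit over 1979 probes with CGGAA, chosen after the data were seen, the same G had -0.298 (SE 0.05, permutation p = 1e-05, the smallest possible). All these fits pool probes with and without M at the C before GGA (105 of 203 with M for CCGGAAG). The seed replacements CGWAAG and CCGWAA keep that C unmodified, so they are unlike comparisons. With M there, CGGAA means were near the array mean of 0 (0.0576 with MG, -0.0237 with MW). Such probes may leave little room for a further fall at other positions. Over 103 probes with CGGAAGT the first C had -2.10 (SE 0.16), and over 32 probes with CCGGAAGT the C at position 2 had -2.12 (SE 0.28), both with adjusted permutation p = 3.5e-05. On the deposited score the coefficient at position 3 of CCGGAAG was 1.68 and passed the limit, as did 0.283 without the dimmest 10% of probes.

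**Figure D3:**
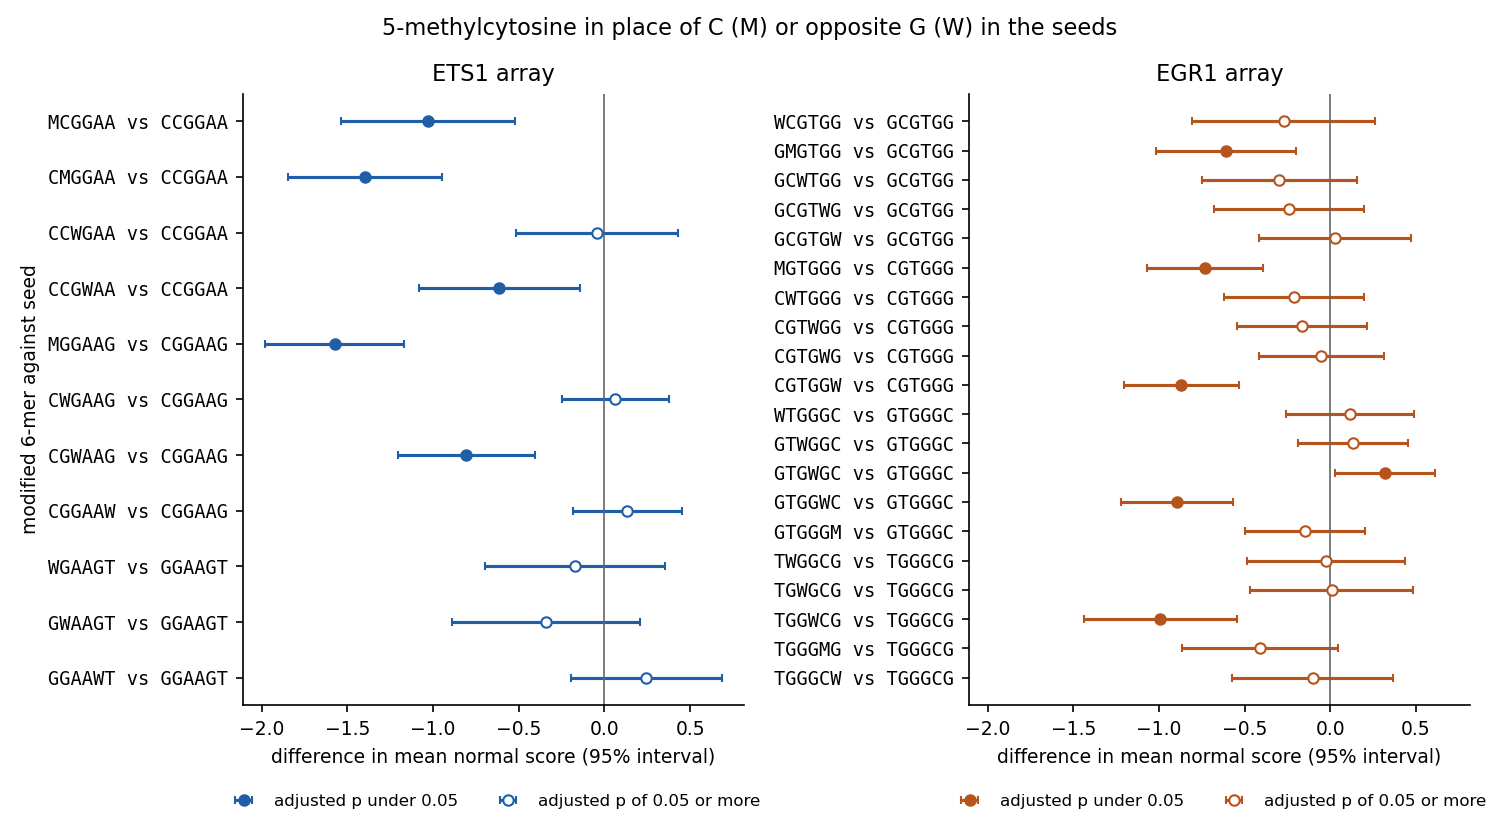
Difference in mean normal score (horizontal axis, bars are 95% intervals) between a seed with 1 modified C (M) or 1 G opposite 5-methylcytosine (W) and the unmodified seed, with filled points past adjusted p 0.05. On the ETS1 array 5 of 11 lie below 0 past the limit, and on the EGR1 array 5 of 20 lie below and 1 above.

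EGR1 bound sites built on the GTGGG of its 9-letter site and runs of G. Of 53 6-mers with E above 0.45, 33 held GTGGG (against 0.819% of all 6-mers), 36 held TGGG and 12 held GGGG. The count of 53 was 31 with letter composition removed, 35 without the brightest 1% of probes, 35 without probes holding a further site, and 87 with sites before the middle of the probe. The highest unmodified ones by E were CGTGGG (E 0.486, mean 2.04 ± 0.75, n = 39), GTGGGC (E 0.475, 1.77 ± 0.80, n = 43), GCGTGG (E 0.472, 1.64 ± 1.06, n = 43), GGGGGC (E 0.460, 1.71 ± 0.56, n = 47) and GGGGCG (E 0.458, 1.38 ± 1.09, n = 50). The highest modified ones were CGTWGG (E 0.487, 1.88 ± 0.97, n = 41), CWTGWG (E 0.487, 2.01 ± 0.75, n = 48), CGTGWG (E 0.483, 1.99 ± 0.88, n = 38), CWTGGG (E 0.481, 1.83 ± 1.12, n = 43) and WTGWGC (E 0.4801, 1.98 ± 0.50, n = 39). By number of modified letters, 9 of 2080 6-mers with 0 passed the E limit (0.433%), 22 of 6144 with 1 (0.358%), 17 of 7728 with 2 (0.220%) and 5 of 5120 with 3 (0.0977%), and 0 with more. Among the 53, means from odd-numbered and from even-numbered probes correlated with r = 0.183 across 6-mers (0.685 among the 58 of ETS1). The order of these EGR1 sites is therefore loosely determined. Over all 23436 6-mers the same r was 0.668 for EGR1 and 0.336 for ETS1.

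Methylation of the CpG on both strands moved no EGR1 6-mer past adjusted p 0.05 (0 of 553), with 20 higher and 18 lower at an unadjusted p under 0.05 in the permutation test. The rank test and the median called 1 lower each, odd-numbered probes 2 lower, letter composition removed 2 higher, and the whole probe 3 higher and 1 lower. The whole-probe search adds CG sites from the constant GCG ends, which have no MW counterpart. GCGTGG had 1.64 with CG and 1.02 ± 0.94 with MW (n = 36), a difference of -0.616 (SE 0.22, adjusted permutation p = 0.492). CGTGGG differed by -0.470 (SE 0.16, adjusted permutation p = 0.461) and TGGGCG by -0.350 (SE 0.23, adjusted p = 0.782). With 5-methylcytosine on 1 strand, 1 comparison passed: MGTGGG had 1.31 ± 0.80 (n = 42), a difference of -0.730 from CGTGGG (SE 0.17, adjusted permutation p = 0.0442). This call ended in 8 of 13 alternatives, while the same difference tested among the seed replacements passed in 12 of 12 (from -2.25 on the deposited score to -0.511). Over the family, each 6-mer read on its alphabetically first strand, MG gave 17 higher and 18 lower at an unadjusted p under 0.05, and CW 8 higher and 20 lower. Read so, the fall of MGTGGG counts as CW. In simulated data a shift of 0.5 on this array was recovered for 5 of 50 6-mers, so differences of that size may have gone undetected in this family. Because planted shifts overlapped on shared probes, that number may understate the power. Planted shifts were also many, which eases the adjustment, so for a family with few shifts it may overstate the power.

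EGR1 scores fell at 2 places when seeds were modified. Replacements by other bases lowered the score in 92 of 100 cases. The lowest of each seed were CTTGGG (-2.11, SE 0.19), TGGMCG (-1.88, SE 0.24), GTGAGC (-1.84, SE 0.21) and GCTTGG (-1.81, SE 0.24). Among 20 replacements by the modified form of the same base, 5 lowered the score. The G at the end of GTGGG was the place in 3 of them, TGGWCG (-0.992), GTGGWC (-0.896) and CGTGGW (-0.869), and the first C of the 9-letter site in MGTGGG (-0.730) and GMGTGG (-0.608, adjusted permutation p = 0.00634). TGGWCG did not pass with odd-numbered probes (-0.5585). The call of GMGTGG ended in 4 of 12 alternatives, and over the whole probe its difference was 0.0237. That search adds unmodified GCGTGG sites that begin in the constant GCG, so the value does not single out 5-methylcytosine. GTGWGC rose by 0.320 over GTGGGC (SE 0.15, adjusted permutation p = 0.0433), a call that ended in 7 of 12 alternatives. The other highest replacements of their seeds did not pass the limit: GCGTGW (0.0260), CGTGWG (-0.0529) and TGWGCG (0.0077).

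In the longer EGR1 sites, 38 probes held GCGTGGGCG, and 5-methylcytosine opposite the G of position 7 gave -1.12 (SE 0.17, adjusted permutation p = 5.2e-05). At the C of position 2 it gave -0.670 (SE 0.17, adjusted permutation p = 0.00026). Opposite the G of position 6 it gave 0.392 (SE 0.16, adjusted permutation p = 0.0265), and the other 5 positions did not pass. Position 6 did not pass in the shorter sites, which more probes hold: 0.0525 in GCGTGGG, 0.1096 in CGTGGGC and 0.0050 in GTGGGCG. Over the whole probe the 9-letter site had 0.0719 at position 6, not past the limit, and -0.255 at position 2, where GCGTGGG had -0.166. Those fits include sites that overlap the unmodified constant GCG at the edge of the probe. Over 416 probes with GTGGGCG the G of position 7 had -1.04 (SE 0.06), and the C of position 8 had -0.163 (SE 0.06, adjusted permutation p = 0.0165). In GCGTGGG (398 probes) position 7 had -0.698 (SE 0.07), position 2 had -0.534 (SE 0.07) and position 3 had -0.298 (SE 0.07, adjusted permutation p = 0.000149). In CGTGGGC (401 probes) positions 7, 2 and 8 had -1.05, -0.330 and -0.219, all past the limit. Position 3 did not pass in CGTGGGC (-0.0731, adjusted permutation p = 0.521) or GTGGGCG (-0.0531, adjusted p = 0.536). Over 11 alternatives the number of lower EGR1 coefficients past the limit ran from 4 (without the brightest 1% of probes) to 11.

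**Figure D4:**
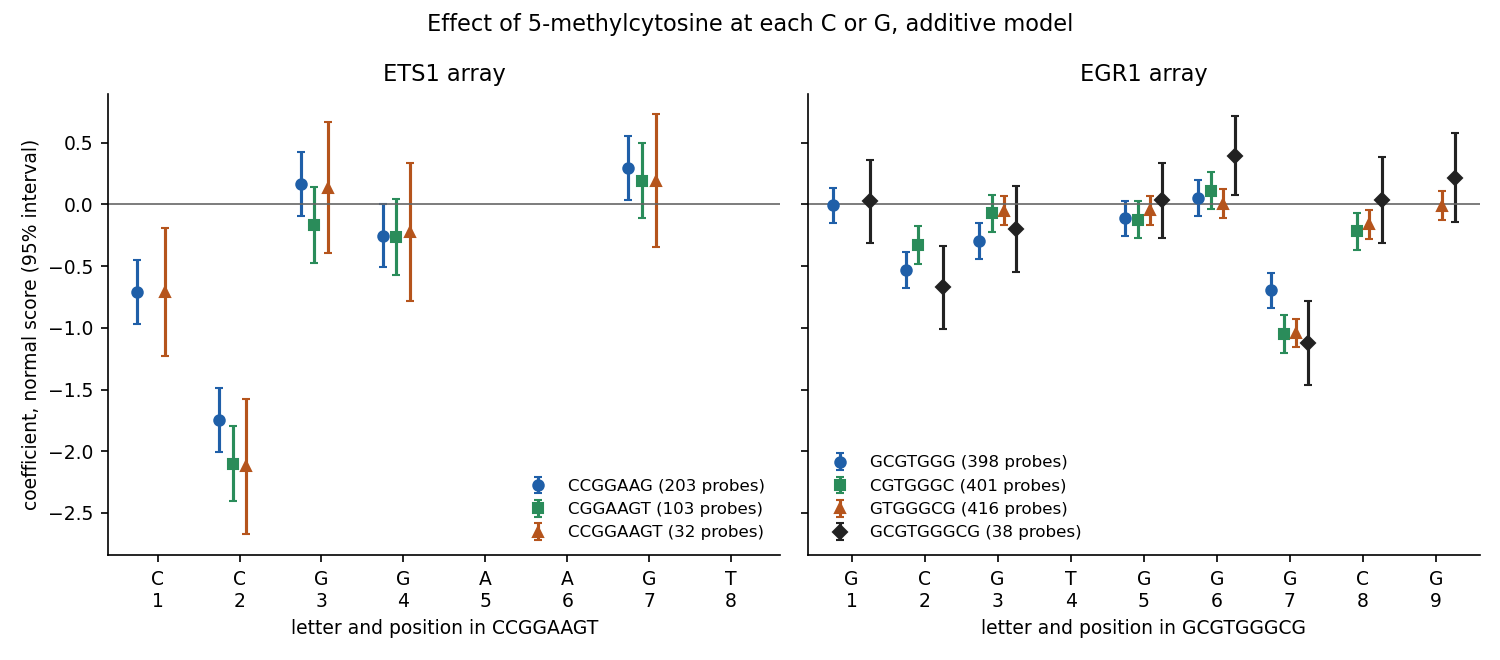
Coefficient of 5-methylcytosine at each C or opposite each G (vertical axis in normal score units, bars are 95% intervals) by position in the longest site of each protein, with 1 marker per fitted site. The lowest ETS1 values lie at position 2, from -1.75 to -2.12, and the lowest EGR1 values at position 7, from -0.698 to -1.12.

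5-methylcytosine opposite a G scored above thymine in the same place at most G positions of the seeds. In this comparison the G itself is replaced by A. Each difference thus includes the loss of that G and does not single out 5-methylcytosine from thymine. On the ETS1 array W was higher than A at 8 of 8 G positions of the seeds, from 0.575 for GGAAWT to 2.15 for CCWGAA. Over the C and G positions together, the ETS1 count ran from 5 (odd-numbered probes) to 9 over 12 alternatives. On the EGR1 array W was higher than A at 12 of 16 G positions, up to 2.16 for GTGWGC. Not past were GTGGWC at 0.362 (adjusted permutation p = 0.0563), TGGWCG at 0.181 (adjusted p = 0.432), WCGTGG at 0.314 (adjusted p = 0.343) and TGGGCW at -0.0217 (adjusted p = 0.968). At the C positions M was above T at 1 of 3 for ETS1 (CMGGAA, 0.472, adjusted permutation p = 0.0307) and at 0 of 4 for EGR1, where GMGTGG differed by 0.0261 from GTGTGG (adjusted p = 0.968) and MGTGGG by -0.206 from TGTGGG (adjusted p = 0.347).

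Across all probes, the normal score changed by -0.0090 per modified letter on the ETS1 array (95% bootstrap interval from -0.0127 to -0.0051) and by 0.0393 on the EGR1 array (0.0356 to 0.0432). Pearson's r across probes was -0.0213 and Spearman's rho -0.0140 for ETS1 (permutation p = 0.0001 and 0.0023), and r and rho were both 0.0927 for EGR1 (permutation p = 0.0001 each, the smallest 10000 permutations can give). Probes are not replicates. On the median the ETS1 slope was -0.0031 and no longer excluded 0. In a fit on letter counts, each C, G, M and W in place of a T raised the EGR1 score by 0.2005, 0.1812, 0.1333 and 0.1245, and the ETS1 score by 0.0747, 0.0621, 0.0220 and 0.0230.

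Each protein's own core set stood apart on its own array. The 48 unmodified 6-mers with GGAA had a median 0.462 above all 2080 on the ETS1 array (percentile 100 of 10000 random sets), and 0.0432 on the EGR1 array (percentile 76.4). The 36 6-mers with 5 or more letters of GCGTGGGCG lay 1.09 above on the EGR1 array (percentile 100) and 0.147 above on the ETS1 array (percentile 99.95). The last value turned to -0.0061 with letter composition removed. No 6-mer passed the E limit on both arrays, where independent lists would share 0.0519 unmodified and 0.0948 modified ones. Mean scores correlated across 6-mers with r = 0.344 (rho = 0.423) among the unmodified and r = 0.294 (rho = 0.322) among the modified, and 6-mers are not independent replicates. With letter composition removed r was 0.0458 and 0.119. On the deposited score it fell as well, to 0.0651 among the modified, so r depends on the scale too.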

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

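The test that sets the EGR1 array against the ETS1 shift was chosen after the result was seen, as were the tests of the difference between the arrays.

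The slope of the normal score on the number of modified letters differed between the proteins by -0.0484 per letter (-0.0090 on the ETS1 array and 0.0393 on the EGR1 array). Swapping the arrays at random within each probe gave p = 1e-04, the smallest that 10000 permutations can give. It compares 2 arrays and not repeated experiments. Modified letters stand in place of A and T as well as C and G, so the slope mixes letter preference with modification. In the fit on letter counts M lay below C and W below G on both arrays. Against T, C and M had 0.0747 and 0.0220 for ETS1, and 0.2005 and 0.1333 for EGR1. G and W had 0.0621 and 0.0230 for ETS1, and 0.1812 and 0.1245 for EGR1. The signs of the slopes alone thus cannot tell the direction of an effect of modification.

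The shift of the CpG family with 5-methylcytosine on both strands differed by -0.1845 (median of the paired differences, permutation p = 1e-05, the smallest possible). The median difference of MW from CG was -0.171 on the ETS1 array, with 400 of 553 6-mers lower, and -0.0041 on the EGR1 array, with 278 lower. The 6-mers overlap, so the p-value is too small by an unknown amount. Over 485 6-mers without GGA the ETS1 median was -0.153 (95% interval from -0.176 to -0.125), which argues against an origin in 6-mers with GGA alone. 6-mers with other parts of the core, such as CCGGCC, stayed among the 485. Flanking letters that complete a GGA on the probe were not set apart either, so partial cores stay open. The EGR1 family showed no net fall, with a median of -0.00413 (interval from -0.0328 to 0.0300). A lowering shared by both arrays cannot be judged from it. In the fit on letter counts M lay below C and W below G on both. Letter composition stays open: with it removed the ETS1 median was -0.0845 (interval from -0.106 to -0.0579), between the bounds set beforehand, and the EGR1 median moved to 0.128. That a general preference for unmodified C and G accounts for part of the ETS1 shift remains a hypothesis. The fit gave that preference for EGR1 too, whose family showed no net fall before composition was removed. The letter fit also uses the same probes, core sites included, so it cannot separate composition from effects at the core.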

How the results depend on the processing

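Under the alternatives, 291 values of main results and 421 of single sites held, while 72 main values moved, 5 weakened and 1 reversed. A count held if it stayed within 1.5 times the main count, a tested value if it kept its direction and side of the limit or passed in neither setting, and r if it stayed within its 95% interval. Among single sites 17 weakened, 6 strengthened and 2 reversed. For reference, the CpG tests called 28 ETS1 6-mers lower with MW, 9 with MG and 7 with CW, and 0, 0 and 1 for EGR1; E passed 58 and 53; the models called 5 and 10 coefficients lower; and r was 0.344 and 0.294. The odd, even and middle-of-probe settings use fewer probes per site. The whole-probe setting adds sites that overlap the unmodified GCG ends, so modified and unmodified forms lie at unlike places. Leaving out the brightest 1% or the dimmest 10% of probes selects them by the score that is tested. The first of these cuts removes strongly bound probes: 95 of the 100 brightest ETS1 probes held GGAA or GGAT. Calls lost without the brightest 1% can therefore follow from the cut itself. For the other changes the cause was not tested. MG and CW follow the alphabetically first strand of each 6-mer here, so the 1 EGR1 call with CW is that of MGTGGG. The ETS1 MW count ran from 2 to 28 over 16 alternatives. No paired analysis was possible because each protein has 1 array and so no replicate numbers to pair, and none could be left out. Probes shared by the arrays were paired only in the difference between them. The alternatives on repeat spots and on zero or negative values were not run, since no probe is listed again and a standardised score has no true zero. The slope with letter composition removed is 0 by construction and was dropped once seen. Each probe carries 1 spot per array, which limits the precision.

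Below, higher, lower and above are numbers of 6-mers or sites past the limit. With the median, the values were ETS1 slope per modified letter -0.0031, ETS1 MW higher 1, EGR1 MW lower 1 and r of the arrays over modified 6-mers 0.2722. On the deposited score, the values were ETS1 CW lower 3, EGR1 CW lower 0, EGR1 core set on the ETS1 array 0.0329, r of the arrays over unmodified 6-mers 0.0675 and r of the arrays over modified 6-mers 0.0651. With letter composition removed, the values were ETS1 MW higher 1, ETS1 MW lower 16, ETS1 CW lower 3, EGR1 6-mers above the E limit 31 and EGR1 MW higher 2. Also different there were EGR1 CW lower 0, EGR1 core set on the ETS1 array -0.0061, r of the arrays over unmodified 6-mers 0.0458 and r of the arrays over modified 6-mers 0.1191. Over the whole probe, the values were ETS1 CW lower 4, EGR1 MW higher 3, EGR1 MW lower 1, EGR1 MG higher 4 and EGR1 CW lower 0. Beside these stood EGR1 WCGTGG against GCGTGG 0.4232, EGR1 GMGTGG against GCGTGG 0.0237 and EGR1 core set on the ETS1 array 0.0644. With sites before the middle of the probe, the values were ETS1 MW lower 11, ETS1 MG higher 1, ETS1 MG lower 3, ETS1 CW lower 1 and ETS1 model coefficients lower 3. Other values in that setting were EGR1 6-mers above the E limit 87, EGR1 CW lower 0, EGR1 model coefficients lower 6, EGR1 core set on the ETS1 array 0.0518 and r of the arrays over unmodified 6-mers 0.2761. The last value there was r of the arrays over modified 6-mers 0.2619. With sites after the middle, the values were ETS1 MW lower 10, ETS1 MG lower 2, ETS1 CW lower 0, EGR1 CW lower 0 and r of the arrays over unmodified 6-mers 0.3012. Also different there was r of the arrays over modified 6-mers 0.2300. Without probes holding a further site, the value was EGR1 6-mers above the E limit 35. Without the brightest 1% of probes, the values were ETS1 6-mers above the E limit 29, ETS1 MW lower 16, ETS1 MG lower 4, ETS1 modified own letters lower 3 and ETS1 model coefficients lower 3. Beside these stood EGR1 6-mers above the E limit 35, EGR1 CW lower 0, EGR1 model coefficients lower 4 and r of the arrays over modified 6-mers 0.3201. Without the dimmest 10% of probes, the values were r of the arrays over unmodified 6-mers 0.2576 and r of the arrays over modified 6-mers 0.2409. With odd-numbered probes, the values were ETS1 MW lower 9, ETS1 MG lower 5, ETS1 CW lower 2, ETS1 5-methylcytosine above thymine 5 and EGR1 MW lower 2. Other values in that setting were EGR1 CW lower 0, EGR1 modified own letters lower 3, EGR1 model coefficients lower 6, r of the arrays over unmodified 6-mers 0.2945 and r of the arrays over modified 6-mers 0.2499. With even-numbered probes, the values were ETS1 MW lower 7, ETS1 MG lower 5, ETS1 CW lower 0, ETS1 model coefficients lower 3 and EGR1 MG lower 1. The rest there were EGR1 core set on the ETS1 array 0.0944 and r of the arrays over modified 6-mers 0.2403. With the local median subtracted, the value was EGR1 CW lower 0. By the rank test, the value was EGR1 MW lower 1. At an E limit of 0.40, the values were ETS1 6-mers above the E limit 104 and EGR1 6-mers above the E limit 236. At an E limit of 0.48, the values were ETS1 6-mers above the E limit 15 and EGR1 6-mers above the E limit 6. At an adjusted p limit of 0.01, the value was ETS1 MW lower 14. Over 6-mers without GGA alone, chosen after the data were seen, the value was ETS1 MW lower 2.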

Other observations

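The comparisons of position and strand in the probe, the site pairs, the counts of letters among sites above the E limit, the product term for the CpG, and the counts among the brightest probes were chosen after results were seen.

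Among 6-mers above the E limit, no modified letter stood at the places with the lowest model coefficients, the C of CGGA for ETS1 and the last G of GTGGG for EGR1. Of 40 ETS1 6-mers with CGGA, 0 had M at the C, although 428 of 858 such 6-mers do, while 19 had W at the next G and 11 at the G after it. Of 33 EGR1 6-mers with GTGGG, 0 had W at the last G (96 of 192 do), and 15, 12 and 15 had W at the other 3 G positions. With TGGGC, 0 of 17 had W at the last G and 6 had M at the C. The first G of GTGGG and the C of TGGGC were thus modified in some of these 6-mers, although single models gave lower scores there.

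EGR1 scores also depended on where the site lay in the probe. Among probes with 1 GTGGG (any letters modified except the last G), sites before the middle of the probe had a mean of 1.45 (n = 917) against 1.27 after it (n = 998), a difference of 0.183 (SE 0.0386, permutation p = 1e-05, the smallest possible). GTGGG on the listed strand had a mean of 1.24 against 1.47 on its reverse, a difference of -0.229 (SE 0.0384, permutation p = 1e-05). For CGGAA with an unmodified C on the ETS1 array the differences were 0.0263 (p = 0.736) and -0.0241 (p = 0.757) in the same permutation tests. Which end of the probe is attached to the slide is not given in the sources used here. Of 8 pairs of sites, CWGATW was above CGGATG by 0.7125 (adjusted permutation p = 0.00324) and GTGWGC above GTGGWC by 1.22 (adjusted p = 8e-05), and the other 6 did not pass. The pairs were picked after their means had been seen on the same probes, and the adjustment does not cover that choice.

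ETS1 sites with CGGAA had lower means with MW than with MG, -0.0237 (n = 486) against 0.0576 (n = 503), but the difference of -0.0813 did not pass (permutation p = 0.211), so a further fall on both strands was not established. The MG mean already lay near the array mean of 0. This test and the product term may thus have had little room to show a further fall, and they do not exclude one. At 3 single sites the MG means were higher (0.513 for MGGAAG, 0.688 for CMGGAA and 0.202 for MGGAAA). There the difference of MW from MG went the same way and was larger, -0.566 for MWGAAG, -0.494 for CMWGAA and -0.489 for MWGAAA (permutation p = 0.027, 0.0474 and 0.0314, adjusted p = 0.0565, 0.0632 and 0.0565), so a further fall stays open there. The product term was -0.155 (permutation p = 0.124) on the normal score and -0.261 (interval from -0.762 to 0.240, p = 0.316) on the deposited score. How to read that test was settled after its value was seen, because the term passed on neither scale and scale could not be judged from it. Saturation of strong sites may hide an effect of CW, but in the weaker 8 contexts the median difference of CW from CG was -0.1357 (range from -0.433 to 0.251), which lies between the bounds set beforehand.

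Of the 100 brightest ETS1 probes, 95 held GGAA or GGAT, against 25.2% of all probes, and 5 did not, among them 2 of the brightest 5; for EGR1, 98 of 100 held TGGG or GGGG, against 49.1%. The 5 ETS1 probes without the core could be spots that spill over, sequences bright on any array, or other binding. Their neighbours had a median percentile 4.13 above that of neighbours of bright probes with the core (interval from -10.6 to 11.5, permutation p = 0.794). Their median percentile on the EGR1 array was 63.4 (interval from 22.4 to 95.1). With 5 probes neither test decides, and no biological explanation was tested.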
